A study of Mus musculus with 6 samples.

How the data were processed

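RNA from mature thymic NKT cells of 3 DOCK8-deficient and 3 wild type samples was hybridised to Illumina mouse arrays, 1 array per sample, after preparation of biotin-labelled cRNA, per the labels' protocols. Samples were assigned to groups by their titles. The deposited scanner table gives an intensity for each of 45281 probes on each array, on a linear scale and, from its values, without background subtraction. Beside each intensity stands a detection p-value, per the file headers. The deposited series table holds values on a log2 scale, as judged from their range. Within each array they rank the probes as the scanner intensities do (rank correlation 0.999999), and array medians lie between 6.14 and 6.22. How the authors normalized that table is not given in the sources used here. Genes in it were not centred, and the direction of its values is that of the intensities.

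The analysis started from the scanner intensities. They were background corrected and quantile normalized with limma's neqc (limma 3.58.1, R 4.3.3), which fits a normexp model to negative controls inferred from the detection p-values, adds an offset of 16 and takes log2. Of the 45281 probes, 34885 carried 1 gene symbol in the platform annotation, 18 carried several and 10378 were not listed with a gene. Probes of the last 2 kinds were left out of the gene tests. Gene identifiers of 34807 of the named probes were found in the RefSeq table of mouse assembly GRCm38.p6, which was used for names and gene order, without coordinates, since the array's build is not given in the sources used here.

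A probe entered the test when its detection p was under 0.05 on at least 3 of the 6 arrays, whatever their group. For a gene with several such probes the one with the highest mean over the 6 arrays was used, which left 9060 genes. Among the 77 genes named by the rule given below, 27 had another detected probe, 52 probes in all. Of these 52 probes, 11 differed in the opposite direction from the one used, 0 of them with an adjusted p under 0.05. That 0 says little about agreement between probes, since only 31 of all 14559 detected named probes passed. Genes named outside the rule were not checked for other probes. The groups were compared with limma (lmFit and eBayes, 2-sided), DOCK8-deficient minus wild type, and p-values were adjusted by the Benjamini-Hochberg method over all genes with a threshold of 0.05. Errors beside log2 differences are moderated standard errors. For a gene detected on no array of a group, the fold is a bound. The brighter group's mean was set against the mean over the dimmer group's arrays of the higher of the gene's own value and the lowest value among detected probes of that array.

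Gene lists were tested with camera (preset correlation between genes of 0.01), camera with an estimated correlation and fry, each list needing at least 5 measured members. The 24 lists were fixed before the data were examined; 1 of them is not reported here, and the others cover NKT transcription factors, NK-type receptors, immature NKT cell genes, cytotoxic effectors, cytokines and chemokines, apoptosis inhibitors and inducers, cytokine receptors and JAK-STAT signalling, integrins and homing receptors, T cell receptor signalling, immediate early genes, cell cycle, interferon-induced genes, glycolysis, oxidative phosphorylation, ribosomal proteins, heat shock, and markers of double-positive thymocytes, naive and regulatory T cells, B cells, myeloid and dendritic cells, thymic stroma and erythroid cells. Of their 664 entries, 63 had no named probe. The fitted model, the sample groups and the rule for naming genes were fixed at the same time. The rule took Dock8, up to 15 rises and 15 falls of largest size among changed genes without overlap between groups, up to 4 changed members per list or else its 2 members of smallest p, and 13 genes tied to NKT cell identity and survival. Genes named outside this rule are said to be so where they appear.

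The functions were tested on simulated data built from the means and spreads of the 9060 genes, with 200 genes changed in each of 20 runs. The test found 22.2% of genes changed by 1.5-fold, 85.1% of those changed by 2-fold and 99.5% of those changed by 4-fold, and 4.94% of its calls were unchanged genes. A shift of the cell cycle list by 0.3 on the log2 scale was called in 20 of 20 runs. The simulated genes varied independently of each other, whereas the correlation estimated for this list in the data was 0.33. The runs therefore do not show how the gene and list tests behave where genes vary together. The runs also held 200 changed genes each, whereas 33 genes passed in the data. With more changed genes the adjusted threshold is easier to reach, so the shares found may be too high for these data. The number of arrays limits the precision of every value.

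Alternatives fixed beforehand were no background correction, median scaling, the deposited log2 table, no filter and a stricter filter on dim probes (detection p under 0.01), the mean of a gene's probes, every named probe on its own, the replicate number as a block, array weights, a trended robust prior (statmod 1.5.0), an adjusted p under 0.10, an estimated correlation for lists, and each sample left out in turn. A test of every detected probe, named or not, was added after seeing the data. Slide and scan date are not given in the sources used here, so batches were not tested.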

Results

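Gene expression was measured on Illumina mouse arrays in natural killer T (NKT) cells, T cells of limited receptor diversity that recognise lipids presented by CD1d. The cells were mature thymic NKT cells bearing CD44 and NK1.1, from mice of a strain that lacks functional DOCK8 and from wild type mice, both on a C57BL/6 background. DOCK8 is a guanine nucleotide exchange factor that activates CDC42 and acts on the actin cytoskeleton of lymphocytes. Each group held 3 biological replicates, 1 array each, and the labels do not say whether a replicate was 1 animal or a pool, so the p-values measure the spread between these samples. Each array carried 45281 probes, of which between 16496 and 18451 (36.4% to 40.7%) were detected above background. The median signal of an array lay between 183 and 235, and detected probes were 1.85 to 2.10 times as bright in the median as undetected ones.

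Dock8 itself was measured first. Its brightest probe read 9.47 ± 0.05 on the log2 scale in the DOCK8-deficient cells and 9.48 ± 0.20 in wild type cells (SD, n = 3 each), a difference of -0.01 with a 95% interval of -0.33 to 0.32. The other 2 Dock8 probes were dim and differed by 0.41 and 0.37 on the log2 scale, with limma adjusted p of 0.70 and 0.59 over all detected named probes. The sample titles call these cells knockout and the genotype label names a DOCK8-deficient strain, without saying what the mutation does to the transcript or where the probes lie relative to it. The Dock8 signal did not separate the groups, so the grouping rests on the labels alone.

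The main comparison asked which transcripts differ between DOCK8-deficient and wild type mature NKT cells, in a series whose title concerns their survival and function. Genes that rose in DOCK8-deficient cells included Hspa1a and Hspa1b, which encode stress-inducible HSP70 chaperones, and Lmna, which encodes the nuclear lamins A and C. Lmna rose 5.12-fold (log2 difference 2.36 ± 0.20 SE, adjusted p = 0.0078), or 2.18-fold without background correction. Hspa1a was at least 3.66-fold and Hspa1b at least 3.28-fold higher (adjusted p = 8.0e-04 and 0.0024), both undetected on every wild type array. Without background correction they read 1.67-fold and 1.60-fold. Those are no measured sizes, since the wild type signal was not above background, and cannot be ranked against folds of detected genes. Among the falls were the recombination enzyme gene Dntt, undetected on every DOCK8-deficient array and at least 2.42-fold lower (adjusted p = 0.028), and Tgfbr3, the betaglycan co-receptor for TGF-beta, which was 2.89-fold lower (log2 difference -1.53 ± 0.16 SE, adjusted p = 0.025). Of 9060 genes tested with 3 arrays per group, 19 rose and 14 fell at an adjusted p under 0.05, and in all 33 the values of the groups did not overlap.

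The immune receptor and effector genes among the rises were Klri2, a lectin-like receptor of NK cells, at 2.82-fold (adjusted p = 0.037), Cd163l1, a scavenger receptor family member, at 2.65-fold, and the T cell growth factor Il2 at 2.11-fold (log2 difference 1.07 ± 0.15 SE). Tlr1, a Toll-like receptor for bacterial lipopeptides, was at least 1.74-fold higher, whereas Tlr7, the Toll-like receptor for single-stranded RNA, fell 2.85-fold (-1.51 ± 0.20). Zeb2, a zinc finger transcription factor active in the terminal maturation of NK and T cells, rose 2.58-fold (1.37 ± 0.15). Other rises included Pdlim1 and Cobll1, which encode proteins of the actin cytoskeleton, at 2.72-fold and 2.28-fold, the gelatinase gene Mmp9 at 2.21-fold, detected on 1 of the 3 wild type arrays, and the thrombin receptor family gene F2rl2 at 2.13-fold. Emp1 and the riboflavin transporter gene Slc52a3 rose 2.77-fold and 2.74-fold, and the potassium channel gene Kcnc1, undetected on every wild type array, was at least 1.95-fold higher.

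Casp9, the initiator caspase of the mitochondrial death pathway, fell 3.19-fold on its brightest probe (log2 difference -1.67 ± 0.22 SE, adjusted p = 0.030), but its second detected probe differed by 0.12 (adjusted p = 0.82 over all named probes). Sulf2, an extracellular sulfatase of heparan sulfate, was read in the same split way, with -1.29 on its brightest probe and 0.12 on the other (adjusted p = 0.86). Lrig1, an inhibitor of growth factor receptors, fell 3.46-fold and Aldh5a1, a mitochondrial aldehyde dehydrogenase, 3.37-fold, each detected on 1 DOCK8-deficient array. The DNA repair gene Fanci fell 3.22-fold and Pik3ip1, an inhibitor of PI3 kinase, 2.03-fold. The Notch pathway gene Dtx1 fell 1.77-fold and the Ly49 family receptor gene Klra9 1.85-fold (adjusted p = 0.047 and 0.044). The zinc transporter gene Slc39a13, the purine synthesis gene Adssl1 and the ribonuclease gene Rnase6 fell 2.23-fold, 2.20-fold and 1.97-fold. In contrast to Casp9 and Sulf2, the 4 other detected Lmna probes read from 1.67 to 2.59 higher, and the second probes of Adssl1 and Aldh5a1 read -0.99 and -1.25.

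**Figure D1:**
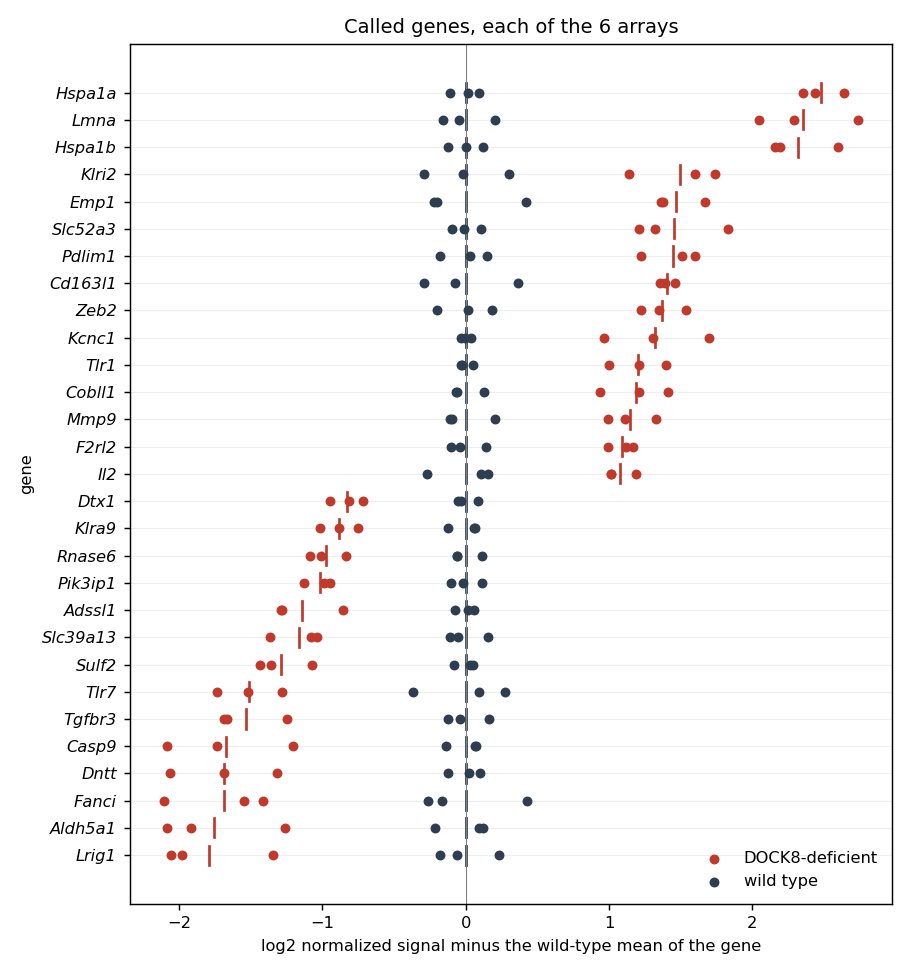
Each row is a gene named among the changed genes, the horizontal axis is the log2 normalized signal minus the gene's mean over the wild type arrays, each point is 1 array and each vertical tick is a group mean. The 3 DOCK8-deficient points lie on 1 side of the 3 wild type points in all 29 rows, but the distance is no measured size for Hspa1a, Hspa1b, Kcnc1 and Tlr1, undetected on all 3 wild type arrays, or for Dntt, undetected on all 3 DOCK8-deficient arrays. Part of the dimmer group's points were undetected for Mmp9, Lrig1, Aldh5a1 and Fanci.

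The count of changed genes depended on each array. With DOCK8-deficient replicate 1, 2 or 3 left out it was 15, 9 or 3, and with wild type replicate 1, 2 or 3 left out it was 3, 3 or 2. All 33 genes kept their direction, which their lack of overlap between groups fixed in advance. They also kept an unadjusted p under 0.05, which their selection on the same arrays made likely. Scaling the arrays to a common median gave 23 genes higher and 39 lower in place of 19 and 14, with 23 of the 33 among them, and Mmp9, F2rl2, Il2, Rnase6, Klra9 and Dtx1 lost their calls (adjusted p from 0.060 to 0.21). Without background correction 17 of the 29 named genes had folds smaller by over 1.5 times, such as 1.49-fold for Lrig1, 1.32-fold for Zeb2 and 1.64-fold for Tgfbr3. Dntt read 1.37-fold there, which is no measured size, since it was undetected on every DOCK8-deficient array. In the same setting Kcnc1, Tlr1, Mmp9 and Rnase6 lost their calls (adjusted p from 0.092 to 0.11). Klra9 and Dtx1 were also lost without the filter on dim probes (0.066 and 0.072), and Casp9 and Sulf2 with the mean of their probes (0.059 and 0.082). Of the 47 other named genes, 11 passed without background correction (Il4, Itga4, Itgae, Cd69, Hivep3, Tnfsf10, Klf6, Stmn1, Ifi47, Bst2 and Uqcrq, with adjusted p from 0.0042 to 0.040).

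Genes tied to NKT cell identity and survival, fixed before the data were examined, did not pass the test over all genes. The gated surface markers Cd44 and Klrb1c, the latter encoding NK1.1, differed by 0.04 and 0.10 on the log2 scale. The value for Cd44 is that of its brightest probe. Its other detected probes read 0.54, 0.37 and 0.15 (limma adjusted p = 0.23, 0.53 and 0.82 over all named probes). The lineage transcription factor genes Zbtb16 and Tbx21 differed by 0.05 and -0.06, and the cytokine receptor genes Il2rb and Il7r by 0.08 and -0.15. For the survival genes the differences were 0.27 for Bcl2 (95% interval -0.11 to 0.65), 0.59 for Bcl2l1 (-0.25 to 1.42) and -0.08 for Mcl1 (-0.39 to 0.23). Those are the brightest probes, and that of Bcl2l1 was detected on 2 of the 3 wild type arrays. Other detected probes read 0.54, 0.08, -0.02, -0.07 and -0.11 for Bcl2 and -0.36 for Bcl2l1 (limma adjusted p from 0.48 to 0.99 over all named probes). Interferon gamma transcript, Ifng, differed by 0.51 (95% interval 0.05 to 0.97, adjusted p = 0.39) and Il4 by -1.25 (-1.89 to -0.60, adjusted p = 0.13). The integrin gene Itgae, which encodes CD103, differed by -0.70 on its brightest probe (-1.04 to -0.37, adjusted p = 0.11). Its other detected probes read from -0.62 to -1.09 (adjusted p from 0.089 to 0.17 over all named probes). The early activation marker Cd69 differed by 0.86 (0.39 to 1.33, adjusted p = 0.15). Il4, Itgae and Cd69 passed without background correction, Itgae at an adjusted p of 0.0091, Il4 at 0.023 and Cd69 at 0.024. They likewise passed in the deposited log2 table (Itgae at 0.027, Il4 at 0.025 and Cd69 at 0.040). Il4 also passed with median scaling (0.0027), and Itgae and Cd69 with a trended robust prior (9.9e-04 and 0.014).

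Of the 24 gene lists fixed beforehand, 22 had enough measured members for limma's camera test, and 7 shifted relative to the other genes with a preset correlation between genes. The cell cycle list rose: 21 of its 24 measured members were higher in DOCK8-deficient cells, with a median log2 difference of 0.33 (camera adjusted p = 4.0e-06, and adjusted p = 0.40 with an estimated correlation). Double-positive thymocyte markers fell, with 9 of 11 measured members lower and a median of -0.36 (adjusted p = 0.0025, and 0.40 with an estimated correlation). The lists of oxidative phosphorylation, myeloid and dendritic cell markers, integrins and homing receptors, heat shock, and immediate early genes shifted upward. With the correlation between genes estimated for each list, 0 lists passed: the adjusted p was 0.64 with an estimated correlation for the immediate early genes and 0.40 for the other 6, while the unadjusted p was under 0.05 for 1 of these 7, the integrins (0.032). By fry's directional test, which does not compare a list with other genes, 2 of the 22 lists passed, the integrins (adjusted p = 0.0073) and heat shock (0.032), and the cell cycle list did not (0.22, and 0.054 by the mixed test).

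In the cell cycle list, which did not pass with its estimated correlation of 0.33 (adjusted p = 0.40), no single gene passed over all genes, and adjusted over the list alone 2 rose: Tk1, thymidine kinase, 1.87-fold (log2 difference 0.91 ± 0.20 SE) and Stmn1, the microtubule regulator stathmin, by 0.85 ± 0.17, with adjusted p of 0.122 and 0.101 over all genes. The Tk1 value is that of its brightest probe. Its other detected probes, both dim, read 0.19 and -0.08 (limma adjusted p = 0.84 and 0.94 over all named probes). The median deviation of the cell cycle list from its genes' means was -0.45 on wild type array 1, 0.04 on wild type array 2 and -0.15 on wild type array 3, against 0.07, 0.16 and 0.30 on the DOCK8-deficient arrays. Oxidative phosphorylation genes had 28 of 36 measured members higher by a median of 0.11 (camera adjusted p = 0.0050, and adjusted p = 0.40 with an estimated correlation). Adjusted over the list alone 1 of them rose, Uqcrq of respiratory complex III, by 1.64-fold, and 0 passed over all genes, Cox7a2 reading 0.36.

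Integrins, homing receptors and adhesion genes had 19 of 25 measured members higher, with a median of 0.13 and camera adjusted p of 0.016 (adjusted p = 0.40 with an estimated correlation). Over all genes 0 members passed, and adjusted over the list alone 6 rose and 1 fell. The fall was Itgae, the alpha chain of the E-cadherin receptor. The rises included Itga4, the alpha 4 integrin of VLA-4, at 3.10-fold (log2 difference 1.63 ± 0.25 SE, adjusted p = 0.056 over all genes), and Cd69. Without background correction Itga4 was 0.87 higher on the log2 scale (adjusted p = 0.0042), and it also passed with median scaling (1.2e-04), in the deposited log2 table (0.0030), with the stricter filter (0.035), with the mean of probes (0.049) and with a trended robust prior (5.8e-04). The other 4, named after their values were seen, were the chemokine receptor genes Ccr6 (1.67 ± 0.39) and Ccr2 (0.99 ± 0.23), the integrin gene Itga2 (0.98 ± 0.23) and the adhesion gene Jaml (0.70 ± 0.16). The list's adjusted p was 0.055 without DOCK8-deficient replicate 1 and 0.055 without the filter on dim probes.

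The heat shock list had 2 rises over all genes, Hspa1a and Hspa1b, and 14 of 16 measured members that did not pass, in both counts (over all genes and adjusted over the list alone). Its median was 0.08 and its camera adjusted p 0.016, with an adjusted p of 0.40 with an estimated correlation and of 0.12 without DOCK8-deficient replicate 1. Hspa1a and Hspa1b are near-identical copies, which the array may not tell apart, so the list tests may count 1 signal as 2. This pair raised the list's mean to 0.33, against its median of 0.08, and the list was not tested without the pair. Immediate early genes, which follow acute stimulation, had 16 of 26 measured members higher with a median of 0.13 (camera adjusted p = 0.026, and adjusted p = 0.64 with an estimated correlation). None of them passed over all genes or adjusted over the list alone, with 0 in both counts in limma and 9 of 26 at an unadjusted p under 0.05 in the upward direction against 2 in the downward one. Klf6 read 0.60 and Cd69 0.86. The call was lost without DOCK8-deficient replicate 1 (adjusted p = 0.19), wild type replicate 1 (0.15) or wild type replicate 3 (0.064), without the filter on dim probes (0.055) and with the stricter one (0.071).

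Markers of other thymic cell types moved both ways. Of the 11 measured markers of double-positive thymocytes, the stage that precedes NKT cell commitment, Dntt fell over all genes and 10 did not pass (adjusted p = 0.40 for the list with an estimated correlation). Adjusted over the list alone 2 fell, Dntt and the lipid-presenting molecule gene Cd1d1 (log2 difference -0.77 ± 0.21 SE, named after its value was seen). Myeloid and dendritic cell markers rose as a list, with 9 of 12 measured members higher, a median of 0.43 and a camera adjusted p of 0.0055 (adjusted p = 0.40 with an estimated correlation). Only 7 of the 12 were detected on every wild type array. The list's members did not pass over all genes, and adjusted over the list alone 1 rose, the Fc receptor gene Fcgr3 (0.84 ± 0.19), with Mpeg1 at 0.76 ± 0.23. The median deviation of this list was 0.53 on DOCK8-deficient array 2, 0.15 on array 1 and -0.14 on array 3 of that group, and the call was lost without DOCK8-deficient replicate 2 (adjusted p = 0.12) or wild type replicate 2 (0.060) and with median scaling (0.058).

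Neither B cell markers nor naive and regulatory T cell markers shifted as lists, with medians of 0.05 over 8 members and 0.00 over 11 members (camera adjusted p = 0.70 for both). The members with the smallest p were Cd74 (0.36) and Ly6d (-0.34) in the former and Satb1 (-0.36) and Il2ra (0.47) in the latter, none passing in either count. Too few members were measured to test erythroid markers (2, Tfrc at 0.53 and Hba-a1 at 0.60) or thymic stroma markers (4, with Ccl25 at 0.32 and Col1a2 at 0.27). Tfrc, the transferrin receptor gene that dividing cells also use, passed adjusted over its list alone.

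**Figure D2:**
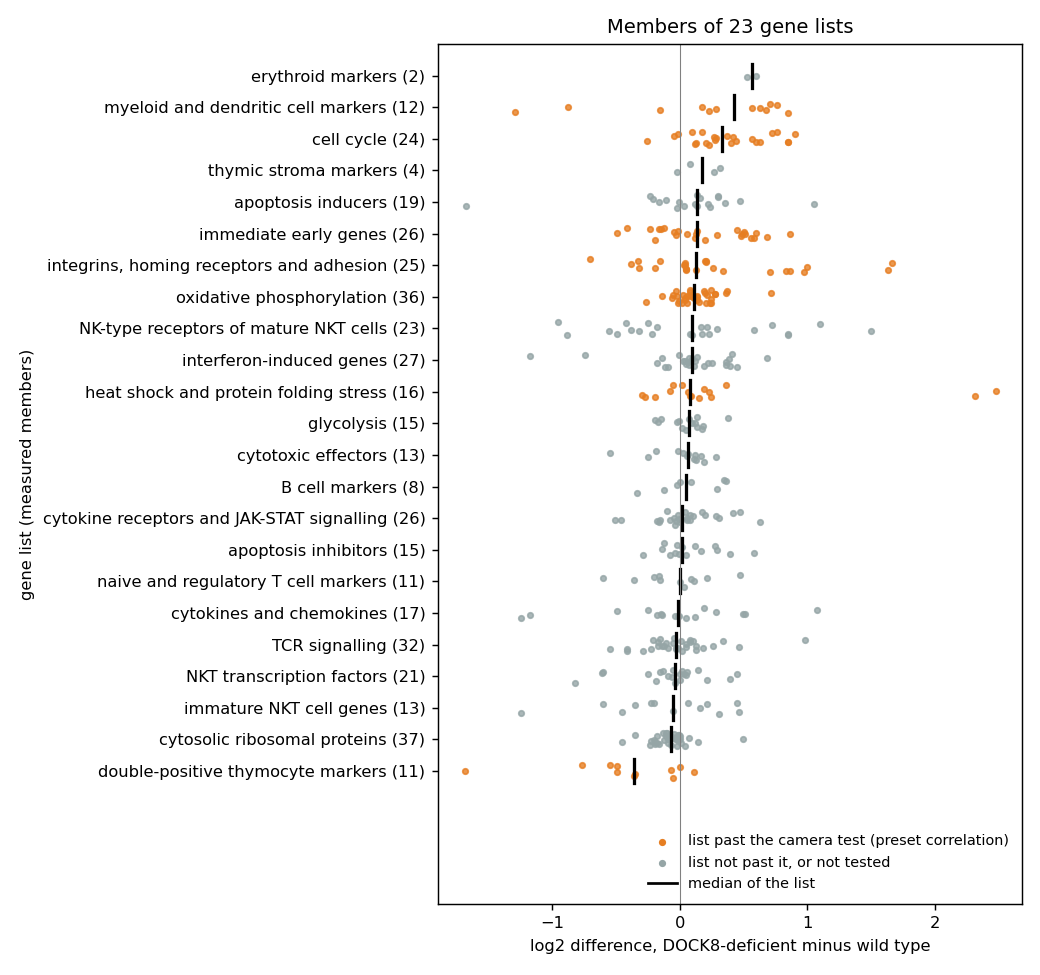
Each row is 1 of 23 gene lists with its number of measured members, each point is 1 gene's log2 difference between DOCK8-deficient and wild type cells (3 arrays each), and the black bar is the list's median. Coloured lists passed the camera test with the preset correlation: 6 lie above 0 in the median and the double-positive thymocyte markers lie at -0.36.

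NK-type receptors did not shift as a list (23 measured members, median 0.10, camera adjusted p = 0.70), with members on both sides. Over all genes Klri2 rose, Klra9 fell and 21 did not pass, and adjusted over the list alone 6 rose and 4 fell. The 6 were Klri2, the signalling adaptor gene Tyrobp (2.14-fold), Klra7 (log2 difference 0.85 ± 0.16 SE), Klrb1f (0.84 ± 0.17), Klre1 (0.72 ± 0.15), and Klrk1, which encodes the activating receptor NKG2D (0.58 ± 0.15). The 4 were all Ly49 family genes, Klra8 (-0.96 ± 0.19), Klra9 (-0.88 ± 0.13), Klra10 (-0.56 ± 0.13) and Klra3 (-0.49 ± 0.12). Apart from Klri2 and Klra9 these genes were named after their values were seen, and Ly49 genes resemble each other closely enough that a probe may read more than 1 of them.

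**Figure D3:**
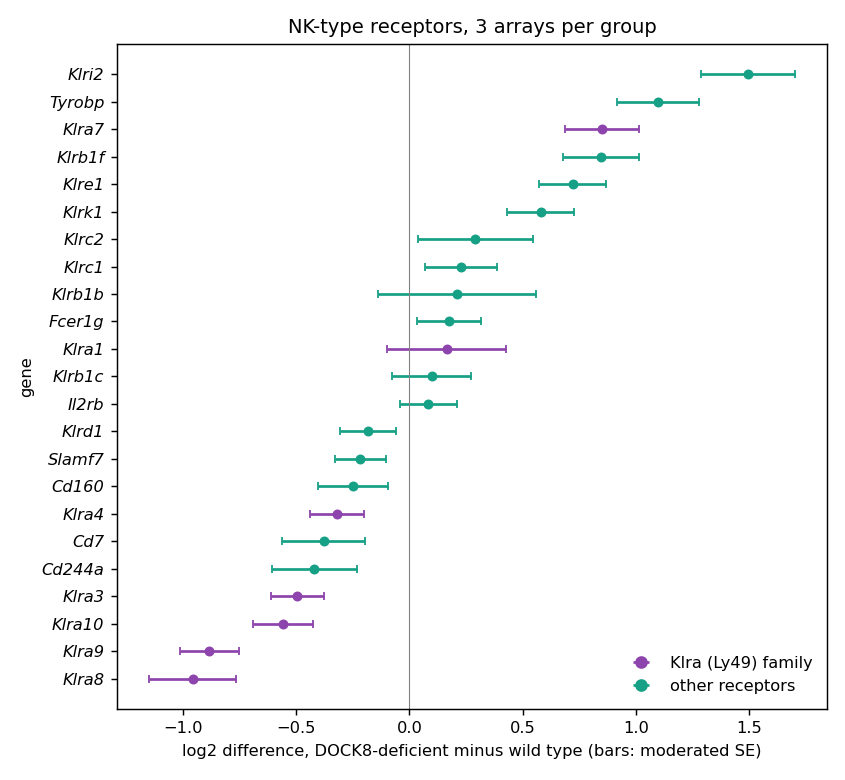
Points are log2 differences between DOCK8-deficient and wild type cells for the 23 measured NK-type receptor genes and bars are moderated standard errors (3 arrays per group). Ly49 (Klra) genes are in purple, with Klra8 lowest at -0.96 and Klra7 at 0.85, and other receptors in green, with Klri2 highest at 2.82-fold on a linear scale.

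The following lists did not pass the camera test. Cytokines and chemokines (17 measured, median -0.02, camera direction upward, adjusted p = 0.77) had 1 rise over all genes, Il2, and 2 rises and 2 falls adjusted over the list alone. Among apoptosis inducers (19 measured, median 0.13, adjusted p = 0.17) Casp9 fell over all genes on its brightest probe and 1 rose and 1 fell adjusted over the list alone. Apoptosis inhibitors (15 measured, median 0.02, adjusted p = 0.68) had 0 members past either count, Cflar reading 0.39 and Bcl2l2 -0.29. Interferon-induced genes (27 measured, median 0.10, adjusted p = 0.096) had 0 past the test over all genes and 1 rise, Bst2 (0.69 ± 0.16), and 1 fall, Ifi47 (-1.18 ± 0.21), adjusted over the list alone. That list passed, upward, without DOCK8-deficient replicate 3 (adjusted p = 0.019) or wild type replicate 3 (0.021), and its adjusted p was 0.64 with an estimated correlation.

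NKT transcription factors (21 measured, median -0.04, adjusted p = 0.68) and immature NKT cell genes (13 measured, median -0.05, adjusted p = 0.70) had 0 members past the test over all genes. Adjusted over each list alone 1 fell in each, Hivep3 (-0.82 ± 0.16), a zinc finger factor, and Il4 (-1.25 ± 0.28), while Egr2 read 0.45. Cytotoxic effectors (13 measured, median 0.06, adjusted p = 0.70) had 1 fall adjusted over the list alone, Tnfsf10, which encodes the death ligand TRAIL (-0.55 ± 0.13), and 0 over all genes, with Lamp2 at 0.28.

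In the following lists of signalling, metabolic and ribosomal genes 0 members passed in either count. T cell receptor signalling genes (32 measured, median -0.03, adjusted p = 0.72) included Cblb at 0.34 and Themis at -0.55. Cytokine receptors and JAK-STAT genes (26 measured, median 0.02, adjusted p = 0.70) included Il21r at -0.46 and Socs3 at 0.63. Glycolysis genes (15 measured, median 0.07, adjusted p = 0.68) included Ldha at 0.38 and Pdk1 at -0.20. Cytosolic ribosomal proteins (37 measured, median -0.07, adjusted p = 0.096) included Rplp0 at 0.50 and Rpl22 at -0.46. This list passed, downward, without background correction (adjusted p = 0.012), in the deposited log2 table (0.0038) and with a trended robust prior (0.011), while its adjusted p was 0.40 with an estimated correlation.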

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

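The test of every detected probe, named or not, was chosen after seeing the data. Counts of changed genes (33, with 19 higher and 14 lower) moved by over 1.5 times with no background correction (124, 66 and 58), median scaling (62, with 39 lower), the deposited log2 table (126, 61 and 65), detection p under 0.01 (53, with 32 higher), a trended robust prior (165, 86 and 79), an adjusted p under 0.10 (109, 59 and 50) and every detected probe (10, 6 and 4). The cause of these moves was not tested. With 1 array left out, and so fewer samples, they ranged from 2 to 15 in all, 2 to 10 higher and 0 to 5 lower. Without a filter, with the mean of a gene's probes, with array weights and with every named probe the counts were 29, 40, 35 and 31. The 33 genes were chosen on these same arrays, so their stability is no independent support. All 33 kept their direction and an unadjusted p under 0.05 under the alternatives tested by gene, but not their calls. Of the 29 named, 4 lost theirs without background correction, 6 with median scaling, 2 without a filter and 2 with the mean of probes, and 18 to 27 with 1 array left out. Of 47 other named genes, 11 gained a call without background correction, 11 in the deposited table, 12 with the trended robust prior and 3 with median scaling. Folds of 17 named genes shrank by over 1.5 times without background correction, of 6 in the deposited table and of 2 with the mean of probes. Those 2 were Casp9 and Sulf2, at -0.77 and -0.58 on the log2 scale. The replicate number as a block gave 0 changed genes, 0 higher and 0 lower in limma, with a lowest adjusted p of 0.054, 833 genes at an unadjusted p under 0.05 and 2 residual degrees of freedom. Same-numbered samples did not deviate together (correlations 0.04, -0.15 and -0.27), which gives no sign that the numbers pair samples. Between differently numbered samples of the groups the correlations ranged from -0.21 to 0.36, the highest for DOCK8-deficient replicate 3 and wild type replicate 2. Whether samples of different numbers share a batch was not tested. With 3 arrays per group these values cannot exclude a pairing. The slide as a block was not run.

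The 7 list calls ranged from 4 to 9 with 1 array left out and became 0 with an estimated correlation, at adjusted p of 0.64 for immediate early genes and 0.400 for cell cycle, double-positive thymocyte markers, oxidative phosphorylation, myeloid and dendritic cell markers, integrins and heat shock. Myeloid and dendritic cell markers read 0.058 with median scaling. Without a filter integrins and immediate early genes both read 0.0546, and the latter 0.071 with detection p under 0.01. With 1 array left out adjusted p ranged from 0.0041 to 0.12 for heat shock, 0.0028 to 0.19 for immediate early genes, 0.0077 to 0.055 for integrins and 2.5e-05 to 0.12 for myeloid and dendritic cell markers. Cytosolic ribosomal proteins gained a call without background correction (0.012), in the deposited table (0.0038) and with the trended robust prior (0.011), and interferon-induced genes without DOCK8-deficient replicate 3 (0.019) or wild type replicate 3 (0.021). Lists that passed under none of these reversed direction: cytokines and chemokines with median scaling (0.59), without a filter (0.68) and with the mean of probes (0.66), and T cell receptor signalling with median scaling (0.95). With 1 array left out their ranges were 0.65 to 0.999 and 0.48 to 0.92, and others that reversed spanned 0.24 to 0.94 for B cell markers, 0.26 to 0.94 for NKT transcription factors, 0.50 to 0.93 for cytotoxic effectors, 0.24 to 0.92 for immature NKT cell genes and 0.43 to 0.88 for naive and regulatory T cell markers.

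Values near 0 also turned sign, none passing the test. Dock8 read 0.26 with the mean of its probes, 0.0049 with array weights and -0.10 to 0.10 with 1 array left out. With median scaling Zbtb16 read -0.014 and Cd44 -0.0015. With 1 array left out Zbtb16 ranged from -0.19 to 0.34, Cd44 from -0.017 to 0.12, Klrb1c from -0.087 to 0.19 and Tbx21 from -0.16 to 0.085. Signal over background of 1.85 to 2.10 limits what dim probes can show.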

Other observations

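The tests named here were chosen after the result was seen, except the other splits of the arrays, the test of all 6 double-positive transcripts and the test of genes neighbouring the receptor genes. By fry's mixed test, which asks whether members changed in either direction and does not compare a list with other genes, 13 of 22 tested lists had an adjusted p under 0.05. Values are given for 3 of them that did not shift by camera. For cytokines and chemokines the mixed adjusted p was 3.5e-05, with Il2 and Lta on the higher side (log2 differences 1.07 and 0.50) and Il4 and Ccl3 on the lower (-1.25 and -1.17), of which Il2 alone passed over all genes. For interferon-induced genes it was 1.1e-04, with Bst2, the tethering factor of budding viruses, at 0.69 and the GTPase gene Ifi47 at -1.18, and 0 members passed over all genes in limma, where 6 were higher and 2 lower at an unadjusted p under 0.05. For apoptosis inducers it was 9.9e-04, with the cell cycle inhibitor gene Cdkn1a at 1.05, which did not pass over all genes (adjusted p = 0.098), and Casp9 at -1.67 on its brightest probe, the one used in this test. The other detected Casp9 probe read 0.12 (adjusted p = 0.82), and with the mean of its probes Casp9 read -0.77 and did not pass (0.059). Lta, Ccl3 and Cdkn1a were named after their values were seen.

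Changed genes outside the naming rule were Lgals1, the lectin galectin-1 (2.07-fold higher), Phf21a, Acot7 and B3gnt5, all higher. Of the 17498 detected probes, 2939 lacked a single gene symbol, and 2 of these passed the test over all detected probes, both lower in DOCK8-deficient cells. Over all 9060 genes, 1550 (17.1%) had groups that did not overlap, where chance gives 10% on average over groupings. A single grouping can lie far from that average where genes vary together. In limma 1028 genes had an unadjusted p under 0.05 with the real grouping, and from 195 to 904 with the other splits of the arrays. With median scaling the real grouping gave 437. The 17.1% is therefore no measure of an effect of the missing DOCK8.

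Other groupings of the arrays called fewer genes: the real grouping called 33 genes and the highest of the other splits 2, so 1 of 10 splits, the real one, reached 33. For lists the real grouping called 7 and the highest other split 6, again 1 of 10. A set of 10 splits is too small for a share under 0.05.

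Hspa1a and Hspa1b were higher in 3 of 3 DOCK8-deficient samples. A candidate explanation is a general heat shock response, as from handling of the cells. It would have raised the other inducible chaperones, whose median log2 difference was 0.147 (7 genes). That lies below the 0.5 set, after the result was seen, as the least size of such a response. The 7 ranged from -0.05 for Bag3 to 0.36 for Hsp90aa1. Their standard error of 0.050 is that of the mean over genes, not of the median and not between samples. The values give no sign of a response of that size, but a smaller general one stays open. A narrower handling effect on Hspa1a and Hspa1b and an effect of the missing DOCK8 also stay open and untested.

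The double-positive thymocyte markers were lower as a list. By camera the list stayed lower under median scaling and without background correction, with an adjusted p of at most 0.0024. Its adjusted p was 0.40 with an estimated correlation. Median scaling decides nothing about scaling between arrays, since a factor common to an array moves the list and the other genes alike. Without background correction the arrays were still quantile normalized, so that setting bears on the background step alone. Fewer double-positive thymocytes among the sorted DOCK8-deficient cells, which the gate on CD44 and NK1.1 would largely remove, may account for the lower list. Over 6 other abundant transcripts of these cells the median was -0.122 ± 0.103. The error here and below is the SE of the mean over genes, not that of the median and not between samples. It lay above the bound of -0.5, but that bound was wrong to use because Rag2 and Cd8a were detected on 0 arrays and show nothing. Over the 4 detected on a wild type array (Rag1 at 7.40, Arpp21 at 7.38, Cd8b1 at 10.46 and Ptcra at 5.32 in wild type) the median was -0.281 ± 0.122, which leaves it open, as does a difference of the NKT cells themselves: 4 of the 11 measured markers also stand in another list and all 11 were detected on every wild type array.

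NK-type receptors lay on both sides, with 6 members higher and 5 lower at an unadjusted p under 0.05. With median scaling 5 lay higher and 4 lower, which decides nothing about scaling between arrays, since a factor common to the genes of an array moves them alike. Signal shared between near-identical Ly49 genes cannot account for the 5 members outside that family, all higher, but for the 7 measured Ly49 genes, 5 lower and 1 higher (Klra7), shared signal and separate changes cannot be told apart with 1 gene on the smaller side. A stretch of another strain's chromosome around the receptor genes could change probes there: 7 of 42 neighbouring genes (16.7%, exact 95% interval 6.97% to 31.4%) had an unadjusted p under 0.05 against 11.3% of all genes (exact binomial p = 0.19, 1-sided), which decides nothing. An effect of the missing DOCK8 on these receptors stays open and untested.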
